A study of Homo sapiens with 6 samples.

How the data were processed

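Expression was measured by RNA sequencing of 6 libraries of A549 cells, 3 transfected with a control siRNA and 3 with an siRNA against NORAD. Per the labels' protocols, cells grown in RPMI-1640 medium were transfected with siRNAs of a single supplier using a lipid reagent, total RNA was extracted with Trizol, ribosomal RNA was depleted, and libraries were made with a strand-specific (directional) kit. The siRNA sequences, the time between transfection and harvest and the sequencing batches are not given in the sources used here. The extraction protocol in the labels speaks of retina, although every sample is labelled A549. Per the submitters' processing notes, FastQC, HISAT2 and HTSeq 0.6.1 were used with the genome build GRCh38. Whether HTSeq counted by strand is not given in the sources used here, so the counts of overlapping genes on opposite strands could be affected. Reads that match more than 1 gene could also affect the counts of near-identical genes, such as ribosomal protein genes and their pseudogenes.

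The deposited table gives, per gene and library, whole-number read counts made by the authors, with no normalization, and FPKM values, also made by the authors, for 29476 genes with Ensembl IDs and symbols. No gene has a count of 0 in every library. The FPKM values deposited by the authors were checked against the counts: count divided by FPKM gave 1 length per gene in all libraries for 100% of values within a tolerance of 0.1%, and these lengths served as gene lengths. Column names matched the sample titles, and 0 columns of other samples were present. All 29476 IDs are in the GENCODE 29 annotation of GRCh38, which gave gene types, coordinates and 3' UTRs. The 3' UTR of a gene was the longest of its basic transcripts, with at least 20 bases after the stop codon. Total counts per library ran from 19332334 to 32760606, at which 1 count is 0.0305 to 0.0517 CPM.

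Libraries were grouped by the treatment in the labels. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr (15515) were scaled with TMM, dispersions were estimated with robust settings, and the quasi-likelihood F test compared si-NORAD with si-NC, two-sided, without covariates (the primary fit). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 of si-NORAD over si-NC, and CPM values use the TMM-scaled library sizes. Confidence intervals take the fitted fold change, its standard error and the moderated degrees of freedom. On simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold in this comparison, run on 15293 genes, the fit recovered 56% and 84% of them with 3 false calls. The simulated counts were drawn independently for each gene around the fitted dispersion trend. They hold no difference among the si-NC libraries, so these shares need not hold for the real libraries.

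Before the data were examined, 29 gene lists with 1097 entries were fixed, of which 1033 were found. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry. With the estimated correlation 0 of the 27 lists passed, with a lowest adjusted p of 0.422. The list of structural small RNAs had 0 tested members, and that of endothelial and erythroid markers had 2, ESAM and KDR, with log2 fold changes of -0.04 and 0.13. Genes with 2 or more TGTA-N-ATA motifs in the 3' UTR were tested with camera and against 10000 matched random sets. Genes named in the text are NORAD, 8 EMT genes, up to 12 called genes with the largest change in each direction and a mean of at least 5 CPM whose groups do not overlap, and, from each list, up to 4 called members or, with none called, up to 2 with the highest CPM. Other genes are said to have been chosen after their values were seen. Not every list member that this rule takes is reported here, and no other gene takes its place.

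Alternatives fixed before the data were examined were edgeR with RLE or upper quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 of FPKM plus 1 or plus 0.1 (FPKM of at least 0.5 in 3 libraries, or no filter), non-robust estimation, the replicate number as a block, protein-coding genes alone, a 1.5-fold threshold, 1 or more motifs, and leaving out each library in turn. Added after seeing the data were a fit with the trend over gene length removed from each library (loess, span 0.3, used as an offset), a fit with si-NC 5 and si-NC 6 left out, in which the lone si-NC library is assumed to vary like the others, and a fit with 1 surrogate variable from svaseq of sva 3.50.0. With si-NC 5 and si-NC 6 left out the spread comes from the si-NORAD libraries alone, so effect sizes are given for that fit. Sequence scans of 3' UTRs and matched random sets were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.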

Results

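RNA sequencing measured gene expression in A549 cells, a human lung adenocarcinoma line, transfected either with a negative control siRNA (si-NC) or with an siRNA against the long noncoding RNA NORAD (si-NORAD). Each group held 3 libraries, numbered 4, 5 and 6 in the labels. Total counts were 20933585, 23539100 and 21688058 in si-NC 4, 5 and 6, and 32760606, 21195218 and 19332334 in si-NORAD 4, 5 and 6. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The design names epithelial-mesenchymal transition (EMT), the change in which epithelial cells lose junctions and gain motility. The comparison of si-NORAD with si-NC asks which transcripts differ between cells given these siRNAs.

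NORAD, an abundant cytoplasmic RNA that binds the RNA-binding Pumilio proteins, was the targeted gene. NORAD (ENSG00000260032, annotated as a lincRNA on the minus strand of chromosome 20, positions 36045622 to 36050960 of GRCh38) was at 550, 461 and 423 CPM (counts scaled by the size of the library) in si-NC 4, 5 and 6 and at 359, 372 and 400 CPM in si-NORAD 4, 5 and 6. The group means were 478 ± 64.8 CPM (SD, n = 3) in si-NC and 377 ± 20.6 CPM (SD, n = 3) in si-NORAD. By CPM, every si-NORAD library was below every si-NC library. In the deposited FPKM, si-NORAD 6 (76.4) lay above si-NC 6 (75.9), so the groups overlapped there. The fitted level was 21.1% lower, with a log2 fold change of -0.34 (SE 0.11) and a 95% confidence interval from -0.59 to -0.10. This difference had an unadjusted p of 0.0109 in the edgeR quasi-likelihood test. It did not pass after Benjamini-Hochberg adjustment over all genes tested (adjusted p = 0.196). It passed with all 6 libraries and no low-count filter (log2 fold change -0.35, adjusted p = 0.0109). It also passed without si-NC 4, where it was smaller (log2 fold change -0.23, adjusted p = 0.00757). With si-NC 5 and si-NC 6 left out, a choice made after seeing the data, it was larger (-0.55). That fit holds 1 si-NC library, so its p does not measure the spread among the si-NC libraries.

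TPM4, which encodes an actin-binding tropomyosin, rose in si-NORAD and was the 1 gene of 15515 tested that passed in the primary edgeR fit, which used TMM scaling, the low-count filter, all 6 libraries and no covariate. TPM4 (ENSG00000167460, chromosome 19, positions 16067021 to 16103005, plus strand) was at 219 ± 6.65 CPM (SD, n = 3) in si-NC and 447 ± 11.7 CPM (SD, n = 3) in si-NORAD, a log2 fold change of 1.03 (SE 0.07, edgeR adjusted p = 0.00282). The next genes by p did not pass in this fit, although DESeq2 called them (adjusted p = 5.54e-16 for GANAB, 1.4e-08 for G3BP2 and 2.29e-09 for LPP). In edgeR, LPP was also called with the replicate number as a block (adjusted p = 0.0261), and with the trend over gene length removed LPP (0.00402), GANAB (0.0046) and G3BP2 (0.0202) were called. With 1 surrogate variable edgeR called 0 genes (1752 at an unadjusted p under 0.05), with TPM4 at a log2 fold change of 1.02 and adjusted p = 0.0666. GANAB, a subunit of the glucosidase that trims glycans in the endoplasmic reticulum, was at 523 ± 16.4 against 834 ± 9.84 CPM (log2 fold change 0.67, adjusted p = 0.0814), G3BP2, a stress granule protein, at 123 ± 6.89 against 185 ± 2.43 CPM (0.59, adjusted p = 0.098), and LPP, a focal adhesion protein, at 76.3 ± 15.3 against 155 ± 4.59 CPM (1.02, adjusted p = 0.098). GANAB, G3BP2 and LPP were chosen after their values were seen. Of all genes tested, 3354 had an unadjusted p under 0.05, where 776 are expected by chance, and 25.4% had groups that did not overlap, where chance gives 10%, with 1963 genes higher and 1972 lower in si-NORAD. The 3 splits that set si-NC 5, si-NC 6 and 1 si-NORAD library against the rest gave 2720, 1892 and 1574 genes with an unadjusted p under 0.05. The other 6 splits gave 92 to 183, so a large part of the excess appears without the treatment grouping where si-NC 5 and si-NC 6 stay together. The count of genes passing depended on the tool and the libraries: DESeq2 called 425 genes (112 higher, 313 lower), edgeR without the low-count filter called 1935, and edgeR called 6251 without si-NC 4, 0 without si-NC 5, 1 without si-NC 6 and 0 without si-NORAD 4, si-NORAD 5 or si-NORAD 6. TPM4 kept a log2 fold change between 1.01 and 1.05 in those 6 fits but lost its call in the 4 that called 0 genes, which had 1384 to 1816 genes with an unadjusted p under 0.05.

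**Figure D1:**
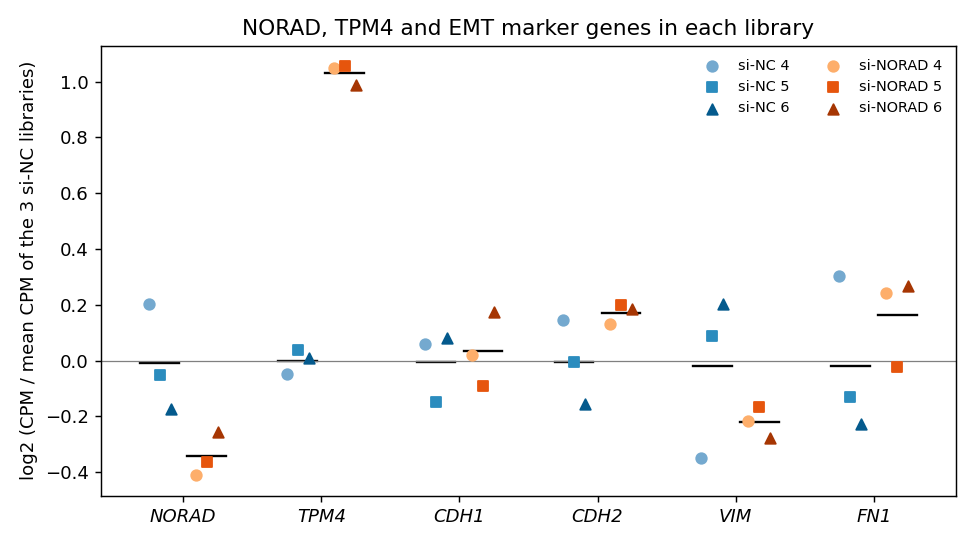
Log2 of each library's CPM over the mean CPM of the 3 si-NC libraries (vertical axis) for NORAD, TPM4 and 4 EMT marker genes (horizontal axis); points are single libraries and bars are the means of the 3 points of a group. The 3 si-NORAD libraries lie below all si-NC libraries for NORAD and above them for TPM4, and the groups overlap for CDH1, CDH2, VIM and FN1.

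None of the 8 EMT genes named in advance passed in the primary edgeR fit. Without si-NC 4 edgeR called 6251 of 15916 genes tested. In that fit 4 of the 8 EMT genes passed: CDH2 (log2 fold change 0.25, adjusted p = 0.00965), VIM (-0.37, 0.000239), FN1 (0.35, 0.00416) and ZEB1 (0.57, 0.000861). With si-NC 5 and si-NC 6 left out, 3 of these 4 turned, with log2 fold changes of 0.13 for VIM, -0.13 for FN1 and -0.12 for ZEB1. CDH1, the epithelial adhesion protein E-cadherin, was at 25.3 ± 2.16 CPM in si-NC and 26.0 ± 2.43 CPM in si-NORAD (SD, n = 3 each), a log2 fold change of 0.04 with a 95% interval from -0.20 to 0.28. CDH2, its mesenchymal counterpart N-cadherin, was at 69.3 ± 7.17 and 78.1 ± 1.97 CPM (0.17, interval -0.03 to 0.37). The intermediate filament gene VIM was at 424 ± 80.9 and 365 ± 13.8 CPM (-0.22, interval -0.52 to 0.08). The matrix gene FN1 was at 158 ± 32.3 and 178 ± 19.1 CPM (0.17, interval -0.15 to 0.49). The transcription factors that repress CDH1 or drive the transition had log2 fold changes of 0.13 for SNAI1, -0.10 for SNAI2, 0.30 for ZEB1 and -0.17 for TWIST1. Adjusted p ranged from 0.289 for CDH2 to 0.848 for CDH1, and the groups overlapped for all 8 genes. The intervals of the primary fit exclude a change of 2-fold or more in any of the 8 genes, at a fitted NORAD level 21.1% lower. In si-NC 4 VIM was at 333 CPM, below all si-NORAD libraries.

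The lists of EMT genes fixed before the data were examined also did not pass. Of 32 tested genes of epithelial junctions and identity, 13 had higher and 19 lower values in si-NORAD, with a median log2 fold change of -0.05 (camera adjusted p = 0.444). KRT8 and KRT7, keratins of simple epithelia, had the highest levels of this list, with log2 fold changes of -0.24 and -0.21. Both passed as lower without si-NC 4 (KRT8 -0.40, adjusted p = 0.00134, and KRT7 -0.27, 0.00135). With si-NC 5 and si-NC 6 left out KRT8 turned, with a log2 fold change of 0.15. Of 36 mesenchymal genes, 24 had higher and 12 lower values, with a median of 0.08 (camera adjusted p = 0.13). This list's direction was the opposite, down, with si-NC 5 and si-NC 6 left out. Its 2 most abundant members, the receptor tyrosine kinase AXL and the matrix gene TGFBI, had log2 fold changes of -0.09 and -0.01. With si-NC 5 and si-NC 6 left out the log2 fold change of AXL was -0.19. In the primary fit, 0 members of either list passed over all genes tested or when adjusted over the list alone. Without the low-count filter edgeR called 4 epithelial genes, all lower, and 7 mesenchymal genes, 5 higher and 2 lower. Without si-NC 4, 6251 of 15916 genes tested were called, 48.3% of them higher. That fit called 14 epithelial genes, 6 higher and 8 lower, and 15 mesenchymal genes, 12 higher and 3 lower. The mesenchymal list was up in that fit but did not pass (camera adjusted p = 0.0547).

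Ribosomal protein genes and nuclear genes of oxidative phosphorylation gave the 2 lowest p of the 27 gene lists tested. Ribosomal protein genes fell as a list in si-NORAD (78 tested, 76 with lower values, median log2 fold change -0.47, camera adjusted p = 3.45e-21), as did nuclear genes of oxidative phosphorylation (75 tested, 68 with lower values, median -0.43, adjusted p = 6.25e-14), while the mitochondrially encoded protein genes rose as a list (12 tested, 11 with higher values, median 0.31, adjusted p = 0.00107). The preset correlation of 0.01 treats the genes of a list as nearly independent. The estimated correlation was 0.91, 0.74 and 0.62 in these 3 lists, so the p-values above overstate the evidence. With the estimated correlation, adjusted p = 0.651 for each of the 3 lists. Fry gave them adjusted p of 0.21, 0.216 and 0.21. RPS2 was at 5667 ± 1103 CPM in si-NC and 4450 ± 107 CPM in si-NORAD, ATP5F1B, a subunit of the ATP synthase, at 1318 ± 102 and 1158 ± 14.1 CPM, and MT-CO1, a subunit of cytochrome oxidase, at 4320 ± 744 and 5454 ± 393 CPM (SD, n = 3 each). Over all genes tested, 0 members of the 3 lists passed in the primary edgeR fit. DESeq2 called 51 ribosomal protein genes and 14 oxidative phosphorylation genes, all lower, and 3 mitochondrially encoded genes, all higher. Without the low-count filter edgeR called 69, 52 and 7 in these directions. Without si-NC 4 edgeR called 75 ribosomal protein genes, all lower, 67 oxidative phosphorylation genes, 66 of them lower, and 5 mitochondrially encoded genes, all higher. The log2 fold change of RPS2 turned (0.00933) with si-NC 5 and si-NC 6 left out. Adjusted over the list alone, 69 ribosomal protein genes and 50 oxidative phosphorylation genes were lower and 5 mitochondrially encoded genes higher. The first 2 of these lists moved with a difference among the si-NC libraries: the median ribosomal protein gene was 0.11 (log2) higher in si-NC 4 than in si-NORAD and 0.62 higher in the mean of si-NC 5 and si-NC 6, and for oxidative phosphorylation these values were 0.04 and 0.58. The mitochondrially encoded list also varied among the si-NC libraries, with medians of -0.20, -0.42 and 0.10 (log2, relative to the mean of the 6 libraries) in si-NC 4, 5 and 6 and of 0.06, 0.18 and 0.30 in si-NORAD 4, 5 and 6, so that the groups overlapped. For the mitochondrially encoded list the median of si-NC 4 minus si-NORAD was -0.36 (log2). That of the mean of si-NC 5 and si-NC 6 minus si-NORAD was -0.31.

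Hypoxia and glycolysis genes fell as a list in si-NORAD. Of 36 tested, 30 had lower values, 22 had every si-NORAD library below every si-NC library, and the median log2 fold change was -0.21 (camera adjusted p = 6.83e-08). With an estimated correlation, adjusted p = 0.422, whereas fry, which asks whether a list's own genes move one way, gave adjusted p = 0.00532. Adjusted over the list alone, 12 genes were lower and 0 higher. Over all genes tested the primary fit called 0 of the list, DESeq2 9 and edgeR without the low-count filter 11, all lower. Without si-NC 4, where 6251 genes were called in all, edgeR called 22 of the list, 20 lower and 2 higher. Among the 12, chosen after their values were seen, were CA9, a carbonic anhydrase induced by hypoxia, at 17.6 ± 4.04 CPM in si-NC and 8.62 ± 1.01 CPM in si-NORAD, EGLN3, an oxygen-sensing prolyl hydroxylase, at 49.6 ± 2.22 and 33.3 ± 2.93 CPM, and BNIP3, a mitophagy receptor, at 156 ± 13.9 and 114 ± 1.44 CPM (SD, n = 3 each). The most abundant members, the glycolytic enzymes PKM and GAPDH, had log2 fold changes of -0.11 and -0.10. These turned for PKM with si-NC 5 and si-NC 6 left out (0.00846) and for GAPDH with the trend over gene length removed (0.0104). The list's median was 0.21 (log2) higher in si-NC 4 than in si-NORAD and 0.19 higher in the mean of si-NC 5 and si-NC 6.

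**Figure D2:**
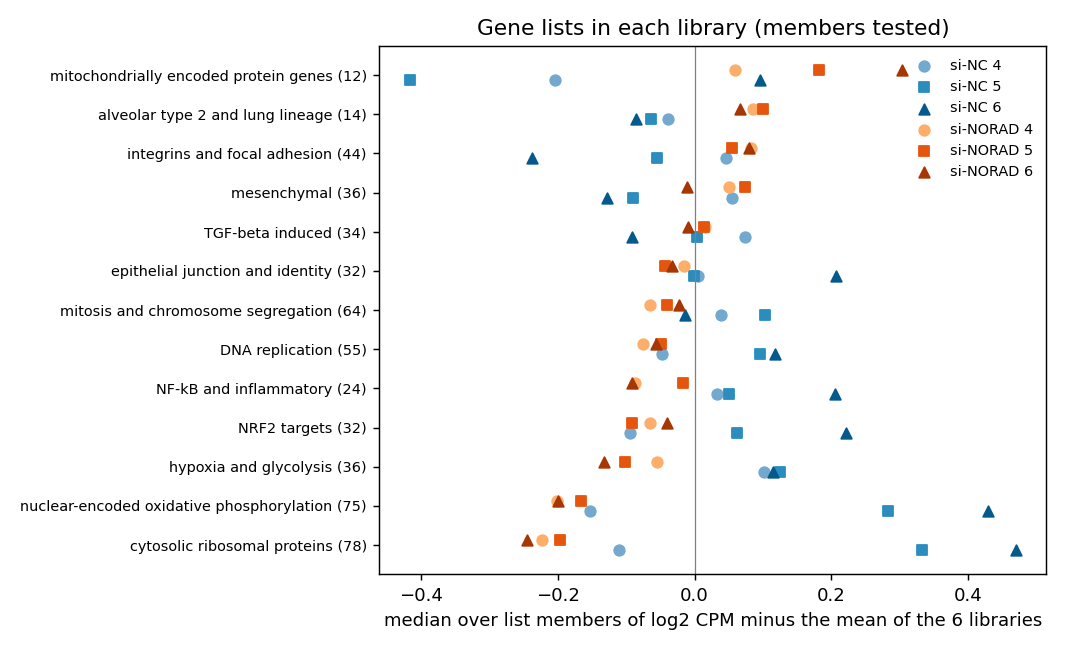
Median over the members of a gene list of log2 CPM minus the mean of the 6 libraries (horizontal axis) for 13 lists (vertical axis, members tested in brackets); points are single libraries. The 3 si-NC libraries lie together for hypoxia and glycolysis, between 0.10 and 0.12, whereas for ribosomal proteins si-NC 4 lies at -0.11 and si-NC 5 and si-NC 6 at 0.33 and 0.47.

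Genes of DNA replication (55 tested, 46 with lower values, camera adjusted p = 0.00118), mitosis and chromosome segregation (64 tested, 43 lower, adjusted p = 0.00772), NRF2 targets (32 tested, 26 lower, adjusted p = 0.00772) and NF-kB and inflammatory genes (24 tested, 15 lower, adjusted p = 0.0315) also fell as lists, and genes of integrins and focal adhesion rose (44 tested, 32 higher, adjusted p = 0.0338). The estimated correlation was -0.01 in the NF-kB list and 0.14 to 0.34 in the other 4, against the preset 0.01. With the estimated correlation, adjusted p = 0.606 for the NF-kB list and 0.651 for the other 4. Fry gave adjusted p of 0.0793 for NF-kB, 0.21 for DNA replication and mitosis and 0.26 for NRF2 and adhesion. Named members did not pass one by one in the primary edgeR fit. The log2 fold changes were -0.18 for MCM7, part of the replicative helicase, and 0.07 for TOP2A, a topoisomerase of dividing cells. They were -0.25 for FTL, a ferritin subunit, -0.47 for CXCL5, a neutrophil chemokine, and 0.38 for FLNA, an actin crosslinker. The other members taken by the rule gave -0.06 for MCM4, 0.10 for NCAPD2, 0.09 for TXNRD1, 0.08 for TNFAIP2 and 0.24 for ACTN4. TOP2A, NCAPD2, TXNRD1 and TNFAIP2 thus moved against their lists. CXCL5 was called by DESeq2 (adjusted p = 0.000118). With si-NC 5 and si-NC 6 left out its log2 fold change was -0.41. In edgeR, CXCL5 and FLNA passed without the low-count filter, and CXCL5, MCM7, FTL and FLNA passed without si-NC 4. FTL (0.012) and TOP2A (-0.10) turned with si-NC 5 and si-NC 6 left out. Adjusted over the list alone in the primary edgeR fit, 2 NF-kB genes and 1 mitosis gene were lower and no gene of the other 3 lists passed. Over all genes tested DESeq2 called 7 mitosis, 2 DNA replication, 1 NRF2 and 1 NF-kB gene, all lower, and 0 adhesion genes. Without si-NC 4 edgeR called 6251 genes in all. Among them were 38 of mitosis (25 lower), 28 of DNA replication (24 lower), 23 of NRF2 (20 lower), 10 of NF-kB (8 lower) and 27 of adhesion (21 higher). Single libraries decided part of the list calls by camera: the NF-kB and mitosis lists did not pass without si-NC 4 (adjusted p = 0.228 and 0.0547). The NRF2 and adhesion lists did not pass without si-NC 6 (0.102 and 0.13), and the adhesion list did not pass without si-NORAD 4 (0.0597). With the trend over gene length removed, mitosis (adjusted p = 0.0534), NF-kB (0.0534), NRF2 (0.0792) and adhesion (0.407) did not pass. The median of the DNA replication list was 0.03 (log2) higher in si-NC 4 than in si-NORAD. In the mean of si-NC 5 and si-NC 6 it was 0.16 higher. The medians of the NRF2 and adhesion lists were 0.00173 and 0.00368 (log2) higher in si-NC 4 than in si-NORAD, and in the mean of si-NC 5 and si-NC 6 they were 0.23 higher and 0.25 lower.

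The other 18 tested lists did not pass camera. The alveolar type 2 and lung lineage list, with CAV1 and LPCAT1 both at a log2 fold change of 0.13, had camera adjusted p = 0.0882 and fry adjusted p = 0.00532, with 10 of 14 genes higher. Camera adjusted p was 0.943 for genes induced by TGF-beta, of which 2 were higher and 5 lower when adjusted over the list alone, 0.106 for components of the TGF-beta pathway, and 0.267 for YAP/TAZ targets and for p53 targets. The list of TGF-beta pathway components passed, with higher values, in the 3 fits on FPKM (adjusted p = 0.0189, 0.0248 and 0.00522) and without si-NC 4 (0.0273). YAP/TAZ targets passed as higher without si-NC 4 (adjusted p = 0.0402). Their median was 0.07 (log2) for si-NC 4 minus si-NORAD and -0.20 for the mean of si-NC 5 and si-NC 6 minus si-NORAD. Cholesterol biosynthesis passed as lower without si-NC 4 (adjusted p = 0.0438) and histones as lower without si-NORAD 4 (0.0425). CDKN1A, the p53-induced cell cycle inhibitor, was at 321 ± 14 CPM in si-NC and 264 ± 9.95 CPM in si-NORAD (SD, n = 3 each; log2 fold change -0.28), with adjusted p = 0.196 in the primary edgeR fit and 0.0283 in DESeq2. Adjusted p was 0.434 for DNA repair, 0.805 for interferon-stimulated genes, 0.174 for the unfolded protein and integrated stress response, 0.288 for cholesterol biosynthesis, 0.823 for Pumilio and NORAD-binding proteins, 0.444 for abundant long noncoding RNAs, 0.175 for replication-dependent histones and 0.328 for immediate early genes. Among the long noncoding RNAs, 5 were higher and 5 lower when adjusted over the list alone, and GAS5 was at 615 ± 74.7 and 451 ± 38.9 CPM and NEAT1 at 515 ± 64.8 and 645 ± 39.0 CPM. Neither passed in the primary edgeR fit (adjusted p = 0.196 for GAS5 and 0.198 for NEAT1), and with the trend over gene length removed the log2 fold change of NEAT1 turned from 0.32 to -0.0263. Without the low-count filter both passed in edgeR, and DESeq2 called GAS5 (adjusted p = 0.0128). Markers of retina, fibroblasts and leukocytes had adjusted p of 0.505, 0.434 and 0.302, with 9, 7 and 7 genes tested. The 24 retina markers present in the table summed to between 12.8 and 16.2 CPM in each library.

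Genes with 2 or more Pumilio motifs (TGTA-N-ATA, where N is any base) in the 3' untranslated region (UTR) had higher values in si-NORAD than other genes. Among 12964 tested genes with an annotated 3' UTR, the 1375 motif genes had a median log2 fold change of 0.11 and the others of -0.02 (camera adjusted p = 1.3e-05, a family of 1 test, and adjusted p = 0.361 with an estimated correlation). Random sets of the same size matched on 3' UTR length and mean expression had a median of 0.09, with a central 95% range from 0.07 to 0.10. Most of the difference was thus shared by genes with long 3' UTRs. The small excess of the motif genes over these sets had a two-sided p of 0.0016 from 10000 random gene sets. That p treats genes as independent and does not measure the spread between libraries. The direction was the opposite with si-NC 5 and si-NC 6 left out, and the difference did not pass after the trend over gene length had been removed (adjusted p = 0.415). Of the motif genes, 0 passed one by one in the primary edgeR fit.

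The libraries differed in ways that the groups do not explain. The first principal component held 55.5% of the variance and set si-NC 5 (21.3) and si-NC 6 (42.2) apart from the other 4 libraries, which lay between -19.2 and -13.2. The counts of si-NC 4 were closer to those of the si-NORAD libraries (chi-square per degree of freedom 5.32 to 6.02) than to si-NC 5 (25.5) or si-NC 6 (51.0), and the 3 pairs of si-NORAD libraries were closest (2.33 to 2.49). No pair of libraries agreed within sampling noise. The difference in part followed gene length: long genes had lower and short genes higher values in si-NC 5 and si-NC 6. Between a gene's length and its deviation from the mean of the 6 libraries, Spearman's rho across genes was -0.32 and -0.44 there. It was 0.31 in si-NC 4 and 0.25 to 0.33 in si-NORAD. Genes are not independent replicates, so these values describe the libraries. With the trend over gene length removed, the first principal component still held 51.6% of the variance. It again set si-NC 5 (20.5) and si-NC 6 (38.2) apart from the other 4 libraries, which lay between -17.9 and -11.5. Ribosomal protein genes took 8.94%, 11.4% and 12.3% of counts in si-NC 4, 5 and 6 and 8.22% to 8.54% in si-NORAD.

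**Figure D3:**
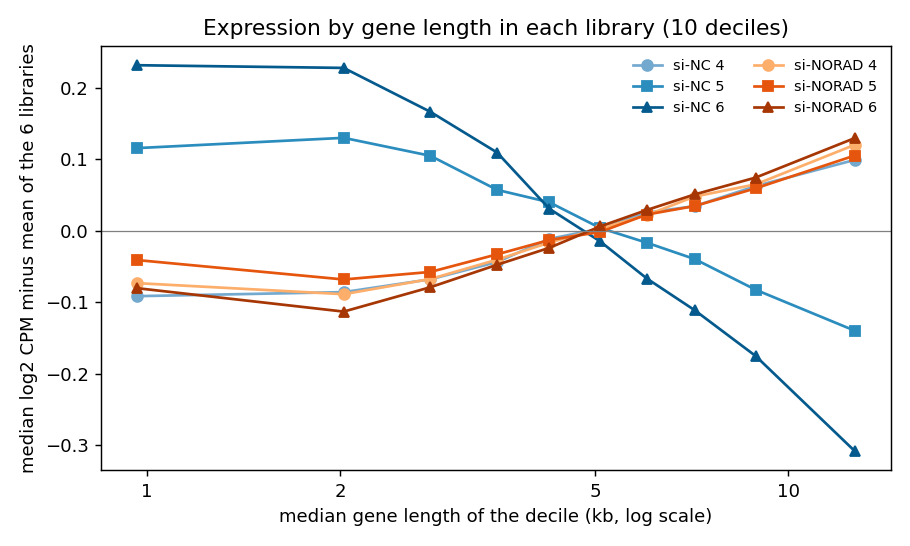
Median log2 CPM minus the mean of the 6 libraries (vertical axis) for genes in 10 deciles of length (horizontal axis, median length in kb on a log scale); each line is 1 library. In the shortest decile si-NC 6 lies at 0.23 and si-NC 4 at -0.09, and in the longest decile si-NC 6 lies at -0.31 and si-NC 4 at 0.10, where the si-NORAD libraries lie between 0.11 and 0.13.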

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

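Removing the gene length trend, leaving out si-NC 5 and si-NC 6, and adding 1 surrogate variable were chosen after seeing the data, and the other alternatives before. The genes called went from 1 to 425 with DESeq2, 1935 without the low-count filter, 2 with limma-voom, 3 with limma on FPKM plus 1 and 3 with FPKM plus 0.1, 6 with the length trend removed (TPM4, LPP, GANAB, NOLC1, G3BP2 and BICD2, all higher, those other than TPM4 chosen after their values were seen), 499 with si-NC 5 and si-NC 6 left out, 0 with 1 surrogate variable (edgeR, 1752 at an unadjusted p under 0.05, TPM4 adjusted p = 0.0666) and 0 to 6251 on leaving out 1 library, the highest without si-NC 4. Those changed at least 2-fold went from 1 to 3, 70, 1, 1, 2, 0, 13, 0 and 0 to 301. NORAD kept its direction in all 20 alternatives that tested it and passed in 3: -0.35 without the filter, -0.55 with si-NC 5 and si-NC 6 left out, and without si-NC 4 in the leave-one-out range of -0.42 to -0.23; it is no protein-coding gene, so that fit has no value. The 9 lists called by camera became 0 with the estimated correlation and 5 with the length trend removed, and ran from 6 to 10 in the other camera tests, with losses of the NF-kB list also without the low-count filter (adjusted p = 0.097), with the filter of 1 CPM (0.0737) and with FPKM and no filter (0.0531), and of the adhesion list with 1 surrogate variable (0.0713). The Pumilio motif p became 0.361 with the estimated correlation and 0.415 with the length trend removed, and its direction turned with si-NC 5 and si-NC 6 left out (p = 0.175), as did that of the mesenchymal list (adjusted p = 0.898). The epithelial list kept its direction and missed the threshold in all 20 alternatives. The set tests have no DESeq2 or non-robust version. Fry called 2 lists, hypoxia and glycolysis and alveolar type 2, the latter not called by camera. For these changes the cause was not tested. TPM4 kept a log2 fold change of 1.02 with 1 surrogate variable, against 1.03 in the primary fit, so that only its call was lost. The replicate numbers gave no sign of pairing: same-numbered libraries had deviations from their group means correlated at -0.03, -0.02 and -0.07. These deviations hold the large difference among the si-NC libraries, so a smaller shared effect could be missed. With the replicate block 2 genes were called (TPM4 and LPP), 2 of them at least 2-fold, with 9 lists.

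Single genes whose log2 fold change turned had not passed in the primary edgeR fit. With si-NC 5 and si-NC 6 left out these were CDH1 (-0.0247), VIM (0.13), FN1 (-0.13), ZEB1 (-0.12), KRT8 (0.15), TGFBI (0.00723), SMAD3 (-0.0202), TOP2A (-0.10), NCAPD2 (-0.0298), XRCC6 (0.0152), TNFRSF10B (-0.14), SLC7A5 (-0.0242), FTL (0.012), TXNRD1 (-0.0456), HMGCS1 (-0.022), PKM (0.00846), RPS2 (0.00933), KHDRBS1 (0.0296), HIST1H2AC (0.0155), EREG (-0.0347), PDE6A (-0.13), TWIST2 (0.0218), ESAM (0.0798) and KDR (-0.22). With the length trend removed they were CDH1 (-0.0107), FN1 (-0.0941), TWIST1 (0.00698), TPM1 (-0.20), SMAD3 (-0.018), GAPDH (0.0104), KHDRBS1 (0.0273), NEAT1 (-0.0263), HIST1H2AC (0.071), TWIST2 (0.0722) and ESAM (0.074). With limma on log2 of FPKM plus 1 they were TGFBI (0.0493), KHDRBS1 (0.0143) and ESAM (0.0177), and with FPKM plus 1 and no filter TGFBI (0.0493), KHDRBS1 (0.0143) and ESAM (0.0177). With FPKM plus 0.1 they were TGFBI (0.0501), KHDRBS1 (0.0145) and ESAM (0.0192). Leaving out 1 library gave ranges across 0 for CDH1 (-0.0337 to 0.0974), HMGCS1 (-0.00503 to 0.0692), KDR (-0.0223 to 0.36), OPN1SW (-0.0605 to 0.26), PDE6A (-0.0454 to 0.44), SNAI2 (-0.21 to 0.05001), TGFBI (-0.0351 to 0.0178), TNFRSF10B (-0.0292 to 0.14), TOP2A (-0.0263 to 0.17), TPM1 (-0.00295 to 0.0546), TWIST2 (-0.20 to 0.0309) and TXNRD1 (-0.00153 to 0.16). In the simulated data, which hold no difference among the si-NC libraries, 84% of 2-fold but 56% of 1.5-fold changes were recovered. Smaller differences were thus often missed even there. The real libraries may give lower shares: LPP, at a log2 fold change of 1.02, had edgeR adjusted p = 0.098 in the primary fit.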

Other observations

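The tests below were chosen after the results they concern had been seen, except the count of gene lists over other splits of the libraries.

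With only 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1 gene in edgeR, 1 of them at least 2-fold, and the highest of the other splits called 0 and 0, so 1 of 10 splits had a count as high for either. DESeq2 called 425 genes in the real split and at most 1 in the others. At an unadjusted p under 0.05 edgeR gave 3354 genes in the real split and at most 2720 in the others, in a split that kept si-NC 5 and si-NC 6 together. For gene lists, the real split called 9 and the highest of the others also 9, so 2 of 10 had a count as high. That other split set si-NC 5, si-NC 6 and si-NORAD 6 against the rest and so kept si-NC 5 and si-NC 6 together.

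The first pattern is the distance of si-NC 5 and si-NC 6 from the other 4 libraries. A trend over gene length was part of it. With the trend removed, the median ribosomal protein gene was still lower in si-NC 4 than in the mean of si-NC 5 and si-NC 6. The difference was -0.35 (log2), against -0.51 before, with an upper quartile of -0.27. These values argue against this gene length as the whole cause. The length is that implied by the deposited counts and FPKM, 5637 bases for RPL4 and 2413 for RPS2. It need not be the length of the transcripts present, so a trend over transcript length stays open. A mislabelled si-NC 4, that is a si-NORAD library under a control label, is argued against by the targeted gene: NORAD was 0.55 (log2) higher in si-NC 4 than in the mean of the si-NORAD libraries, whose SD was 0.08, and above each of them. TPM4 was at 212 CPM in si-NC 4, against 220 to 225 CPM in si-NC 5 and si-NC 6 and 433 to 454 CPM in si-NORAD. It was named from a fit that included si-NC 4, so its value is no separate evidence on the label. Ribosomal protein genes lay nearer to si-NORAD in si-NC 4. Their list median was 0.11 (log2) above si-NORAD there and 0.62 above it in the mean of si-NC 5 and si-NC 6. A difference in RNA integrity, culture or preparation between these libraries could also be the source; no label gives one, and the design names no biological difference among the si-NC libraries, so no biological explanation was tested.

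The second pattern concerns the genes most clearly higher in si-NORAD: of the 20 with the lowest p and an annotated 3' UTR, 12 hold TCGGAGA or CGGAGAA there, against 4.18% of other genes, and of the 20 lowest-p genes that were lower, 1 does; TPM4, G3BP2, LPP and ZNF616 hold TCGGAGAA, GANAB, second by p, holds neither, and those other than TPM4 were chosen after their values were seen. The sites were picked from 4 scans of these same data, followed by rank tests of chosen sequences not kept here, so no p is given. With 3' UTR length alone removed CGGAGAA ranked 13 and TCGGAGA 37 of 16251 behind C-rich sequences such as CCCCTCC. GC content and gene length were also removed in a step added later. They then ranked 1 and 5 in all 6 libraries, by the edgeR test statistic, which is scaled by spread. By plain log2 differences, not scaled by spread, they ranked 1 and 3 against si-NC 4, and 89 and 1425 against si-NC 5 and si-NC 6. Among the 180 sequences with the base composition of TCGGAGA that hold 1 CG, it ranked 1, 1 and 3 in these comparisons; genes with either site had a median log2 fold change of 0.11, against 0.04 to 0.09 in sets matched on 3' UTR length, GC content and gene length, and by site the medians for TCGGAGAA, TCGGAGA and CGGAGAA were 0.07, 0.11 and 0.13 in all 6 libraries and 0.06, 0.03 and 0.05 against si-NC 4, so that only the latter has the longest site highest. A candidate explanation is repression in the si-NC libraries by a strand of the control siRNA beginning TTCTCCGA, the reverse complement, a start recalled from a widely used control siRNA; the sequence used in this study is not given in the sources used here. As the sites were chosen for the pattern, these values decide neither for this explanation nor against 3' UTR length, GC content or gene length, and all stay open.

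The third pattern is the lower level of hypoxia and glycolysis genes in si-NORAD. The gene length trend is argued against as the whole cause. The list's median was -0.22 (log2) with the trend removed and -0.21 before, with an upper quartile of -0.12 after removal. That length is again the one implied by the deposited FPKM, so a trend over transcript length stays open. The distance of si-NC 5 and si-NC 6 stays open as a contributor: in si-NORAD against si-NC 4, 33 of 36 genes were lower and the median was -0.21, outside the range of -0.04 to 0.03 of 10000 random lists matched on expression, but 1 si-NC library carries this comparison and the random lists hold no shared regulation. An effect of NORAD silencing, an effect of either siRNA unrelated to NORAD and a difference in cell density or oxygen between the cultures stay open; the design has 1 siRNA per group as labelled, so it could not separate the first from the second, and the third was not tested.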
